A study of Mus musculus with 10 samples.

How the data were processed

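Islets were isolated from female mice aged 5 weeks, 5 heterozygous for Men1 and 5 wildtype littermates, and total RNA from about 100 islets per mouse was prepared with a column kit and checked on a Bioanalyzer, per the labels' protocols. An input of 100 ng of RNA was amplified over 2 cycles to biotinylated cRNA, per the labels' protocols, a step that shortens transcripts and can enlarge differences between small samples. Each sample was hybridised to 1 Affymetrix Mouse Genome array. The deposited values are on the log2 scale, 1 value per probe set and array, and were made with GCRMA, per the submitters' processing notes. GCRMA adjusts the background by probe sequence, normalizes arrays to one another and summarises probes, which pulls dim probe sets towards a common low value and makes array medians alike. The scanner and the version of the software are not given in the sources used here. The log2 scale was read from the deposited values themselves, which ran from 0.654 to 17.58 with array medians from 3.28 to 3.40 and no negative value.

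Groups were taken from the sample labels, and all 10 arrays entered the comparison. Probe sets were named through a platform annotation table: 34958 carry 1 gene symbol, 932 carry several and were not named, and 9211 are unnamed here. Symbols were checked through gene identifiers against the RefSeq genes of assembly GRCm38.p6, where 34754 matched and 0 symbols needed updating. No coordinates are given, since the values name no genome build. After leaving out 64 control probe sets, a probe set was kept if its log2 value was above 4 on at least 5 of the 10 arrays. This left 18567 probe sets, of which 16575 carry 1 symbol, for 10538 genes.

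The difference between genotypes was fitted per probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets kept, with a threshold of 0.05. All p-values are two-sided. Of the gene lists, 29 were fixed before the data were examined, as were the test, the filter, the threshold, the rule for named genes and the alternatives other than 2 named later. A list entered with 1 probe set per gene, the one with the highest mean, and 25 lists had at least 5 measured members. These were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists, and set beside camera with an estimated correlation, fry, and an exact permutation test of the list mean per mouse over the 252 assignments of 5 of 10 arrays, whose smallest possible p is 0.00794. Some members of the lists lack a name in the annotation table and are not analysed here, Ins1 and Mafa among them. Some genes stand in more than 1 list, such as Igf2 in the growth factor and imprinted lists.

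Genes were named by a fixed rule. It took Men1, up to 12 genes per direction that pass the threshold, filled up to 6 by p among genes whose groups do not overlap if fewer pass, the 2 members of each list with the smallest p where none passes (up to 4 where some do), and 9 hormone and cell cycle genes where measured. Pdgfra was named in addition because it passed when adjusted over its list alone. Kdr and the Igfbp genes were named after their values were seen.

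The fit was tested on simulated data of 18567 probe sets with the means and residual SDs of these arrays, independent noise between genes and 200 changed, 50 per fold size, in 10 simulations. It recovered 31.8% of 1.5-fold, 74.6% of 2-fold, 91.4% of 3-fold and 96.2% of 4-fold changes, with 8.8 false calls on average. Recovery with fewer changed genes, where the adjusted threshold is harder to reach, was not simulated. A list shifted by 0.5 was called in 10 of 10 simulations. Since genes of a cell type vary together in real tissue, this says nothing of how often correlated lists are called without a shift.

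The alternatives were no filter and a stricter filter on dim probe sets, a further quantile normalization, median centring, a trended and robust variance prior, array weights, the replicate number as a block, the acinar list mean or the 3' minus 5' difference of control probe sets as a covariate, leaving out each array, a plain test per probe set, 1 probe set per gene, an adjusted threshold of 0.10, the other list tests, and the mean over all kept probe sets of a gene.

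The stromal list mean as a covariate, and leaving out heterozygous replicates 2 and 5, were added after the data were seen. Correlations between list means over the 10 mice were tested with 100000 permutations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.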

Results

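Gene expression was measured in pancreatic islets of 10 female mice aged 5 weeks, 5 heterozygous for Men1 and 5 wildtype littermates. Men1 encodes menin, a tumour suppressor whose loss leads to endocrine tumours. The islets of each mouse, about 100, gave 1 RNA sample, and each sample was run on 1 short-oligonucleotide array, so that the replicates are separate mice. Of 45037 probe sets without controls, 18567 lay above a log2 value of 4 on at least 5 of the 10 arrays and were compared. Array medians ranged from 3.28 to 3.40, and 18458 to 18890 probe sets per array lay above 4. Arrays correlated with one another at r = 0.962 to 0.988 . All differences are heterozygous minus wildtype on the log2 scale, levels are means ± SD with n = 5 per genotype, and SE is the standard error of a difference.

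Men1 itself was measured first, since it is the targeted gene. Its 1 probe set above background stood at 6.89 ± 0.39 in wildtype islets and 6.42 ± 0.30 in heterozygous islets (SD, n = 5 each). The difference was -0.47 (SE 0.20), which corresponds to 72.3% of the wildtype level with a 95% interval of 53.2% to 98.2%. All 5 heterozygous arrays lay below the wildtype mean, and 2 of the 5 lay below every wildtype array. These 2 were replicates 2 and 5, which also stood apart in lymphocyte markers. Without them, an exclusion chosen after the data were seen for those markers, the difference was -0.28. This exclusion removed low Men1 values from heterozygous islets only. Wildtype replicate 5 was kept, although it had the lowest wildtype Men1 value (6.25, next 6.83). Its lymphocyte mean was also the highest among wildtype arrays (5.32, against 6.81 and 6.54 in the heterozygous arrays left out). The smaller difference therefore cannot be assigned to the lymphocyte markers. On all arrays an exact two-sided permutation test gave p = 0.0635. The limma p of 0.0396 (0.241 without heterozygous replicates 2 and 5) became 0.9999 after adjustment over all probe sets. The other 2 Men1 probe sets lay at background, at 3.17 and 2.55 in wildtype islets and 3.14 and 2.66 in heterozygous islets. The position of these probe sets relative to the deleted part of the gene is not given in the sources used here, so the values are no check of the labels.

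The main comparison asked which transcripts differ in heterozygous islets at an age before tumours are usual. No single gene passed the test, and the 12 genes named here are, in each direction, the 6 with the smallest p among genes whose groups did not overlap. Higher in all 5 heterozygous mice than in any wildtype mouse were Nsun3, a mitochondrial RNA methyltransferase, at 6.89 ± 0.13 against 6.23 ± 0.14 (difference 0.66, SE 0.10), Vldlr, a lipoprotein receptor (0.56, SE 0.12), and Ppig, a peptidyl-prolyl isomerase (0.72, SE 0.15). C230091D08Rik (0.61, SE 0.10), Bicral (0.55, SE 0.12) and the FAD synthase gene Flad1 (0.54, SE 0.12) showed the same separation. C230091D08Rik was dim, at 4.42 ± 0.16 against 3.82 ± 0.13, with its wildtype mean below the filter value of 4. The probe set with the smallest p was taken per gene, and for C230091D08Rik, Vldlr and Ppig it was not the brightest one kept. Lower without overlap were Klf2, a transcription factor of endothelial cells and lymphocytes, at 8.16 ± 0.19 against 9.12 ± 0.50 (-0.96, SE 0.22), Lama4, a laminin chain of vessel walls (-0.60, SE 0.14), the secreted protease gene Htra3 (-0.46, SE 0.12), Plxdc2 (-0.51, SE 0.11) and Septin8 (-0.60, SE 0.15). Mief1, a mitochondrial fission factor, stood at -0.72 (SE 0.15), with another of its probe sets going the other way.

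With limma, 0 of 18567 probe sets passed an adjusted p of 0.05, and the lowest adjusted p was 0.720, for Nsun3. At an unadjusted p under 0.05 there were 760 probe sets where chance gives 928, and a plain per-probe-set test on the same values called 0 after adjustment, with 679 under 0.05. At an unadjusted p under 0.01 there were 135, of which 87 were higher and 48 lower, where chance gives 186. After a further quantile normalization this split was 68 higher and 85 lower, and without heterozygous replicate 4 it was 83 higher and 201 lower of 284. With the acinar mean as a covariate there were 226, and without heterozygous replicates 2 and 5 there were 87. The groups did not overlap in 130 probe sets (0.7002%), where chance gives 0.794%. The median 95% interval reached 0.33 to either side of a difference, or 1.26-fold. In simulated data of the same size 31.8% of 1.5-fold changes and 74.6% of 2-fold changes were recovered. These shares hold for 200 genes changed at once by up to 4-fold, with independent noise between genes. With fewer changed genes the adjusted threshold is harder to reach, and that case was not simulated.

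**Figure D1:**
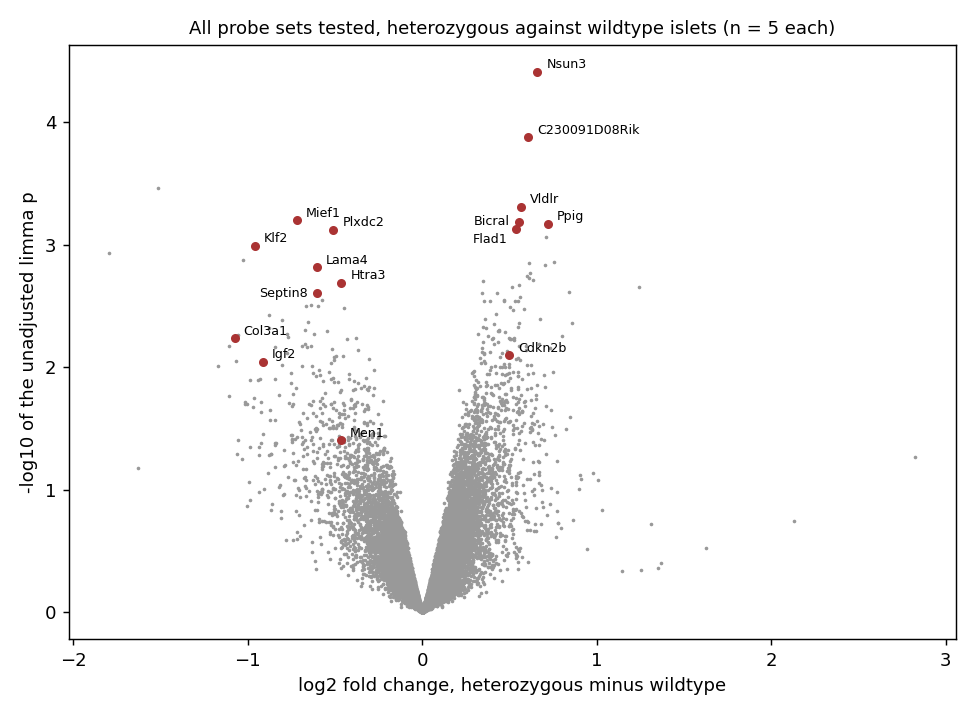
Each point is 1 of the 18567 probe sets, with its log2 fold change (heterozygous minus wildtype, n = 5 each) on the horizontal axis and -log10 of its unadjusted limma p on the vertical axis. Labelled points are Men1, the 6 genes per direction with the smallest p among those without overlap, and Col3a1, Igf2 and Cdkn2b from the gene lists, and none passed an adjusted p of 0.05.

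The measured means of islet hormone genes lay close together in both genotypes, which does not show equal levels where values are compressed or intervals wide. Ins2 was at 16.28 ± 0.073 in wildtype and 16.23 ± 0.024 in heterozygous islets, and Gcg, which encodes glucagon, at 16.40 ± 0.065 and 16.31 ± 0.069. Sst differed by -0.042 (95% interval -0.51 to 0.42) and Ppy by 0.11 (-0.50 to 0.71). Of 17 beta cell genes measured, 7 were higher and 10 lower with a mean difference of -0.012, and the 2 with the smallest p were the transcription factor Isl1 (-0.15, SE 0.18) and the potassium channel gene Kcnj11 (-0.15, SE 0.20). Of 6 alpha cell genes, 2 were higher and 4 lower. Irx1, an alpha cell transcription factor, stood at 6.26 ± 0.15 against 6.71 ± 0.28 (-0.45, SE 0.14), and Gria3, a glutamate receptor subunit, differed by 0.24 (SE 0.18). Of 7 delta, PP and epsilon cell genes 4 were higher and 3 lower, with Hhex at -0.17 (SE 0.15) and Rbp4 at -0.15 (SE 0.19). Of 11 genes of endocrine progenitors 4 were higher and 7 lower, among them the Notch target Hes1 (-0.57, SE 0.23) and Insm1 (0.48, SE 0.29). Of 17 secretory granule and exocytosis genes 9 were higher and 8 lower, with Rab27a at 0.17 (SE 0.11) and Vamp2 at -0.19 (SE 0.16), where another Vamp2 probe set went the other way.

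None of these 5 lists was called by camera, limma's test of a list against all other genes. Its adjusted p was 0.587 for beta cells, 0.107 for alpha cells, 0.620 for delta, PP and epsilon cells, 0.427 for progenitors and 0.852 for secretory granules. The delta, PP and epsilon list had a median of 0.033, a mean of -0.011 and a downward test, and the secretory granule list had a mean of 0.00071 and a downward test. Over all probe sets 0 members passed, and adjusted over the list alone 1 member passed, Irx1 (limma adjusted p = 0.0491). The beta_cell list was called lower without wildtype replicate 2 (-0.11, camera adjusted p = 0.0128), and alpha cells were called lower without wildtype replicate 3 or without the filter on dim probe sets. On all 10 arrays and with an estimated correlation, adjusted p = 0.894 for beta cells and 0.364 for alpha cells. Ins2 and Gcg lie near the top of the measured range, which ended at 17.58, where differences can be compressed.

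Menin acts in a histone methyltransferase complex, and cell cycle inhibitors are among its known targets in islets. Cdkn2b, an inhibitor of CDK4 and CDK6, stood at 7.86 ± 0.15 in heterozygous and 7.36 ± 0.32 in wildtype islets (0.50, SE 0.15), Cdkn1c at -0.34 (SE 0.18), Cdkn1b at 0.036 (95% interval -0.49 to 0.56) and Cdkn2c at -0.016 (-0.31 to 0.28). Of 9 inhibitor genes measured 5 were higher and 4 lower. Of 12 genes listed for the menin complex and related factors 4 were higher and 8 lower, Men1 itself among the lower ones. The histone demethylase gene Kdm6a, one of the related factors, stood at 0.20 (SE 0.10). Among 13 G1 cyclin and kinase genes 7 were higher and 6 lower, with E2f1 at 0.21 (SE 0.12; another probe set went the other way), Ccnd3 at -0.28 (SE 0.17) and Ccnd1 at -0.15 (SE 0.21). Among 19 proliferation genes 7 were higher and 12 lower, with Mki67 at 0.026 (SE 0.23), Racgap1 at 0.24 (SE 0.11) and Cdc20 at -0.27 (SE 0.13). Of the Hox genes and cofactors 4 were measured, too few for a list test, and Hoxa5 stood at -0.47 (SE 0.21) and Hoxc6 at 0.16 (SE 0.14).

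By camera, the adjusted p was 0.620 for the inhibitors, 0.308 for the menin complex, 0.852 for the G1 genes and 0.104 for proliferation. The G1 list had a mean of 0.022 and a downward test. In these lists 0 members passed over all probe sets and 0 adjusted over the list alone. Leaving out single mice called the list proliferation lower without wildtype replicate 2 (camera adjusted p = 0.0494), without wildtype replicate 3 (0.000322) and without heterozygous replicate 4 (0.00338), where all 10 arrays gave adjusted p = 0.719 with an estimated correlation.

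The widest group difference lay in genes of stromal cells, the fibroblasts and mural cells around vessels. All 17 measured members were lower in heterozygous islets, with a mean difference of -0.72 and a list mean of 9.30 ± 0.69 against 10.02 ± 0.32 (SD, n = 5). Col3a1, a fibrillar collagen, stood at 12.06 ± 0.70 against 13.14 ± 0.38 (-1.08, SE 0.31), the proteoglycan gene Dcn at 11.46 ± 0.35 against 12.10 ± 0.30 (-0.64, SE 0.19), and the growth factor receptor gene Pdgfra at -0.78 (SE 0.24). Of 14 endothelial genes 13 were lower, with a mean of -0.31, among them the junction protein gene Esam (-0.53, SE 0.17) and Egfl7 (-0.61, SE 0.24), while Kdr differed by 0.00012 (SE 0.11). Of 11 duct cell genes 9 were lower, with a mean of -0.22, among them the water channel gene Aqp1 (-0.63, SE 0.27) and Anxa1 (-0.74, SE 0.34), both also made outside ducts.

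Camera called all 3 lists lower, with adjusted p = 9.76e-16 for stromal, 7.25e-07 for endothelial and 0.0124 for duct genes. With an estimated correlation between members none of them passed (adjusted p = 0.364 for each). An exact permutation test of the list mean per mouse gave p = 0.0794, 0.0794 and 0.111, and adjusted p = 0.546, 0.546 and 0.556. Over all probe sets 0 members of these lists passed, and adjusted over the list alone 3 stromal members passed, Col3a1, Dcn and Pdgfra (limma adjusted p = 0.0430 each), with 0 endothelial and 0 duct members. In 4 of the 5 heterozygous mice the stromal mean lay between 8.63 and 9.44, below all wildtype mice (9.59 to 10.4), and in heterozygous replicate 4 it stood at 10.4. The list duct_cell was not called without heterozygous replicate 5 (mean -0.17, camera adjusted p = 0.167), without wildtype replicate 4 (-0.16, 0.128), without the filter on dim probe sets (-0.089, 0.0540) or with the acinar mean as a covariate (-0.20, 0.0892). Its call also ended without heterozygous replicates 2 and 5 (-0.19, camera adjusted p = 0.130).

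**Figure D2:**
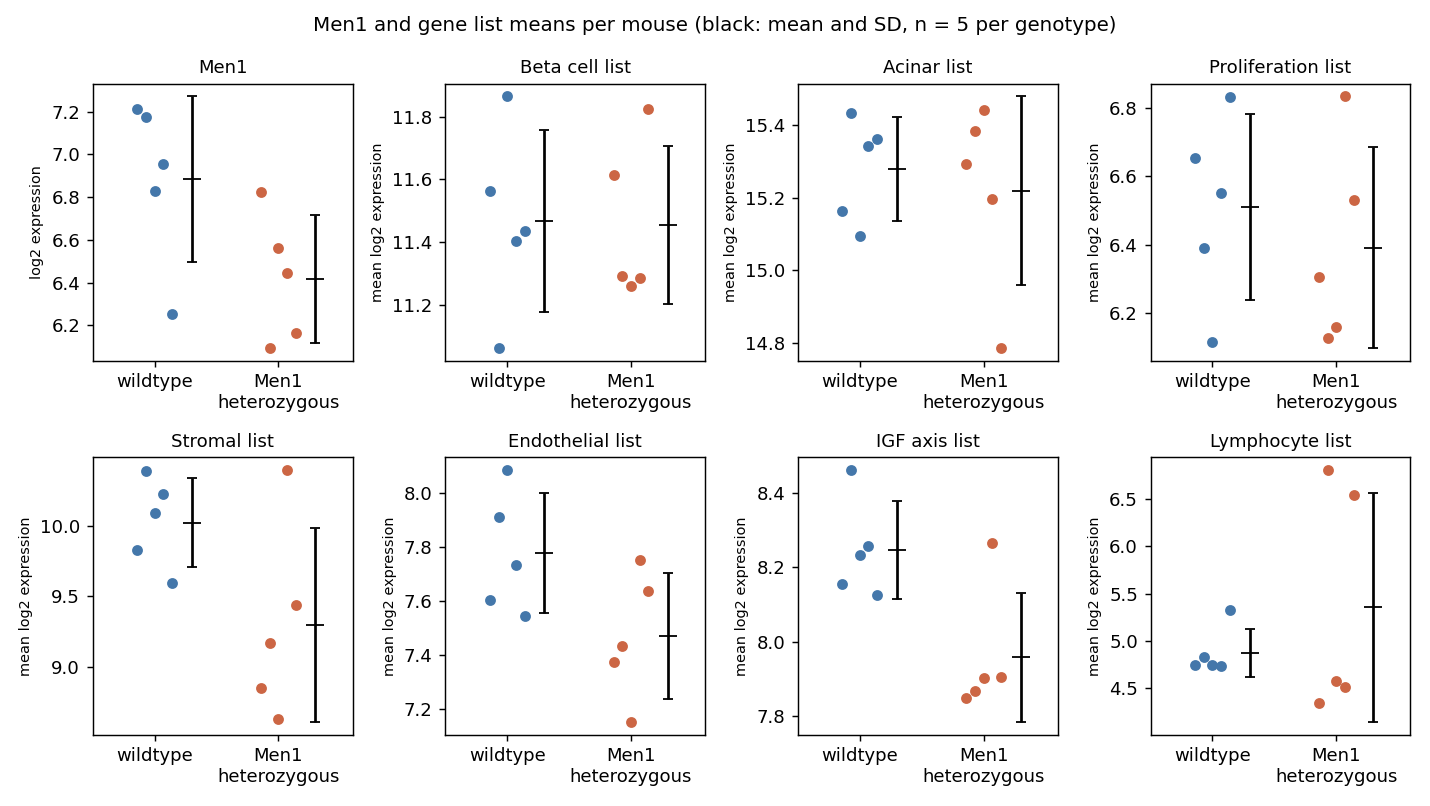
Each point is 1 mouse, with the log2 level of Men1 or the mean log2 level of a gene list on the vertical axis, by genotype, and black marks show mean and SD (n = 5 each). Heterozygous replicate 4 holds the highest stromal mean of the 10 mice (10.4), and the lymphocyte mean is above 6 in heterozygous replicates 2 and 5.

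Among signalling lists, 9 of 12 measured genes of the insulin-like growth factor axis were lower and 3 higher, with a median of -0.40 and a list mean of 7.96 ± 0.17 against 8.25 ± 0.13 (SD, n = 5). Igf2, a fetal growth factor, stood at 5.45 ± 0.66 against 6.37 ± 0.30 (-0.91, SE 0.29), and Igf2r, the receptor that clears it, went the other way at 6.92 ± 0.35 against 6.36 ± 0.094 (0.55, SE 0.15). The binding protein genes Igfbp3, Igfbp4, Igfbp5, Igfbp6 and Igfbp7 were among the lower members, from -0.38 to -0.84. Of 6 hedgehog pathway genes 4 were lower, with a mean of -0.20, led by the co-receptor gene Gas1 at 7.02 ± 0.26 against 7.69 ± 0.39 (-0.67, SE 0.19), and with Sufu at -0.18 (SE 0.089). Of 16 immediate-early genes, which respond to stimulation and handling of cells, 14 were lower with a mean of -0.20, led by Klf4 (-0.69, SE 0.22) and the phosphatase gene Dusp1 (-0.31, SE 0.14).

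Camera called these 3 lists lower, with adjusted p = 0.00544 for the growth factor axis, 0.0379 for hedgehog and 0.00252 for immediate-early genes. None passed with an estimated correlation (adjusted p = 0.226, 0.364 and 0.607), and the exact permutation p of the list means was 0.0397, 0.0873 and 0.397 (adjusted 0.546, 0.546 and 0.709). Adjusted over the list alone 1 hedgehog member passed, Gas1 (limma adjusted p = 0.0300), with 0 in the other 2 lists and 0 over all probe sets. Over the 10 mice the stromal mean correlated with the mean of the growth factor axis at r = 0.919 and with that of hedgehog at r = 0.811. Without heterozygous replicate 5 none of these 3 lists was called, with a mean of -0.28 for the growth factor axis, -0.17 for hedgehog and -0.059 for immediate-early genes. The immediate-early call also ended without wildtype replicate 4 (-0.13), with the acinar mean as a covariate (-0.14) and with array weights (-0.11). The hedgehog call also ended without wildtype replicate 2 (-0.15) or 4 (-0.17), without heterozygous replicate 1 (-0.18) or 2 (-0.18), with the acinar mean as a covariate (-0.19) and after median centring (-0.21), and that of the growth factor axis with the mean of all probe sets per gene (-0.19). Of the 25 lists, 4 were called without heterozygous replicates 2 and 5, stromal and endothelial genes among them, and none of these 3.

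The remaining signalling and stress lists were not called. Of 12 imprinted growth genes 8 were lower (mean -0.15, camera adjusted p = 0.0514), among them Grb10, an adaptor that restrains insulin signalling (-0.28, SE 0.090), and Igf2 again. Of 14 genes of the TGF-beta and activin pathways 9 were lower (-0.21, adjusted p = 0.104), with Id1 at -0.68 (SE 0.26) and Tgfbr2 at -0.51 (SE 0.26). Of 6 Wnt targets 5 were lower (-0.13, adjusted p = 0.182), with Nkd1 at -0.34 (SE 0.21) and Apcdd1 at -0.30 (SE 0.20), where another Apcdd1 probe set went the other way. Of 18 endoplasmic reticulum stress genes 12 were higher (0.10, adjusted p = 0.258), among them the chaperone gene Dnajc3 (0.36, SE 0.15) and Trib3 (0.70, SE 0.30). Of 14 hypoxia and glycolysis genes 9 were higher (0.061, adjusted p = 0.587), with Adm at -0.42 (SE 0.18) and Slc2a1 at 0.29 (SE 0.21), where another Slc2a1 probe set went the other way. Of 11 DNA damage and p53 pathway genes 7 were higher (0.076, adjusted p = 0.308), with Sesn2 at 0.37 (SE 0.14) and Brca2 at 0.23 (SE 0.12). Of 5 prolactin and serotonin genes 3 were higher (0.0044, adjusted p = 0.949), with Stat5b at 0.13 (SE 0.12) and Socs3 at -0.23 (SE 0.22). Single mice decided some of these: imprinted genes were called lower without wildtype replicate 2 or heterozygous replicate 1, TGF-beta genes without wildtype replicate 3 or heterozygous replicate 4, and Wnt targets without heterozygous replicate 4. On all 10 arrays these 3 lists had adjusted p = 0.364, 0.606 and 0.607 with an estimated correlation. In these 7 lists 0 members passed over all probe sets and 0 adjusted over the list alone.

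**Figure D3:**
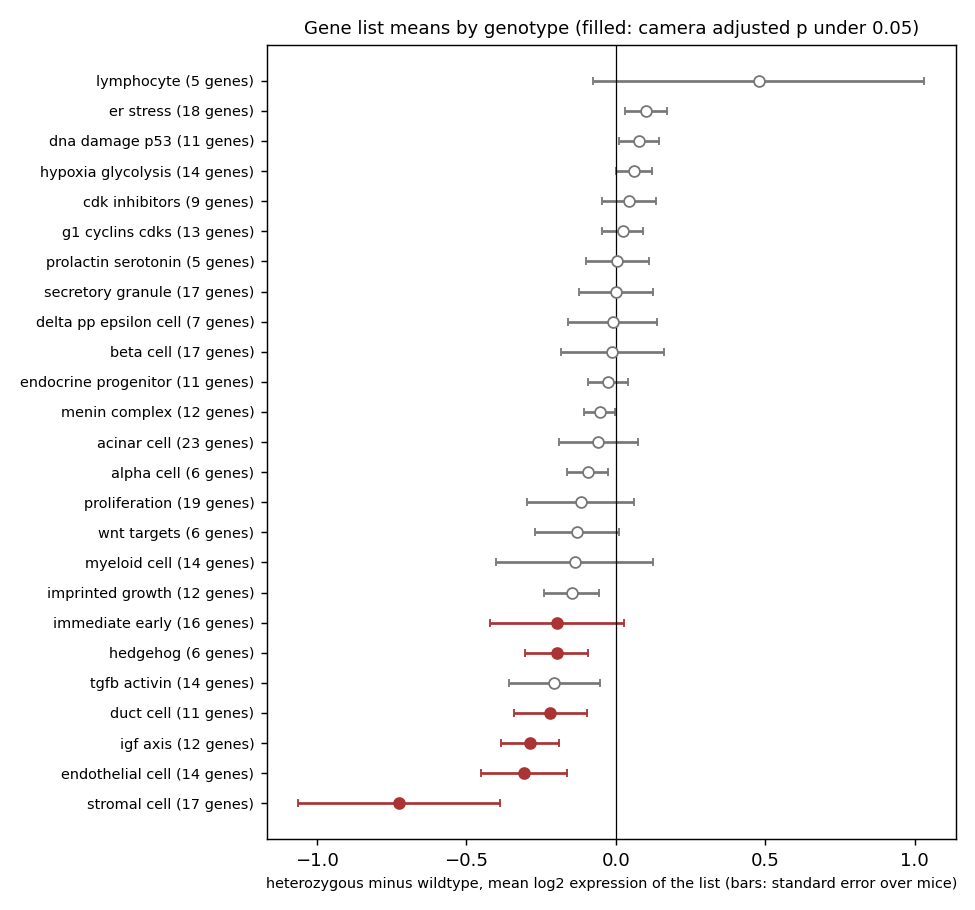
Each point is 1 of the 25 gene lists tested, with the difference of its mean log2 level (heterozygous minus wildtype, n = 5 each) on the horizontal axis and bars of 1 standard error over mice. Filled points are the 6 lists with a camera adjusted p under 0.05, from stromal genes at -0.72 to immediate-early genes at -0.20, and none of them passed with an estimated correlation.

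Other cell types were present in the preparations. Transcripts of acinar cells, the enzyme-secreting cells around islets, stood at 15.28 ± 0.14 in wildtype and 15.22 ± 0.26 in heterozygous islets (SD, n = 5), and 6 of 23 genes were higher and 17 lower (camera adjusted p = 0.226), with the protease gene Ctrc at -0.63 (SE 0.61; -0.029 without wildtype replicate 5) and Reg1 at -0.046 (SE 0.078). Many acinar genes, such as Cela3b at 17.1 over all arrays, lie near the top of the measured range, where differences can be compressed, so that near-equal means do not show equal acinar content. Of 14 myeloid genes 5 were higher and 9 lower (-0.14, adjusted p = 0.107). The 2 with the smallest p were the macrophage genes Mrc1 at 4.73 ± 0.60 against 5.66 ± 0.51 (-0.93, SE 0.31) and Adgre1 at 4.42 ± 0.35 against 4.99 ± 0.37 (-0.57, SE 0.21). Both were dim in heterozygous islets, near the filter value of 4. Of 5 lymphocyte genes 4 were higher (0.48, SE 0.55, adjusted p = 0.411), with the B cell gene Ms4a1 at 1.03 (SE 0.66) and Lmo2 at -0.52 (SE 0.34). Igha, an antibody chain, and Fabp1, made in gut and liver, stood at 13.07 and 12.22 in heterozygous replicate 2, against at most 8.99 and 7.32 on the other arrays. The lymphocyte mean stood at 6.81 and 6.54 in heterozygous replicates 2 and 5 and at 4.34 to 5.32 on the other 8 arrays. The myeloid mean was also highest there among heterozygous mice (8.02 and 7.99), so that leaving out these 2 arrays lowers it by choice, and myeloid_cell was then called lower (-0.49, camera adjusted p = 3.32e-07). The er_stress list was then called higher (0.19, camera adjusted p = 0.0400). On all 10 arrays adjusted p = 0.719 for myeloid and 0.483 for er_stress genes with an estimated correlation. Lists of neural (3 genes), adipocyte (1 gene) and erythroid cells (0 genes) had too few measured members for a test, with Ncam1 at 0.10 (SE 0.15), Cdh19 at -0.052 (SE 0.46) and Fabp4 at -0.32 (SE 0.24). Acinar genes were called lower without wildtype replicate 3, heterozygous replicate 2 or heterozygous replicate 3, and myeloid genes without heterozygous replicate 2. On all 10 arrays adjusted p = 0.846 for acinar genes with an estimated correlation. In these 6 lists 0 members passed over all probe sets and 0 adjusted over the list alone.

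RNA quality was compared through control probe sets at both ends of 2 transcripts. The 3' minus 5' difference was 3.42 ± 0.060 in wildtype and 3.50 ± 0.16 in heterozygous islets for Gapdh (SD, n = 5, exact permutation p = 0.333), and 3.14 ± 0.17 and 3.29 ± 0.27 for Actb (exact permutation p = 0.302). Averaged over both it stood at 3.56 and 3.59 in heterozygous replicates 3 and 4, which held the lowest and the highest stromal mean, and at 3.21 to 3.37 on the other 8 arrays. The first principal component held 27.6% of the variance, the second 16.3% and the third 12.1%, with exact permutation p = 0.960, 0.302 and 0.0873 between the genotypes.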

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

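The tests that use the 3' minus 5' difference, the acinar mean or the stromal mean as a covariate were read for these patterns after the results were seen, and the stromal covariate was added after the data were examined.

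In 8 of 212 groups of 5 arrays, where chance gives 10.6, 1 array lay apart from the other 4 by most of the group's range. In heterozygous islets these were Hoxa5 at 6.545 in replicate 5 (nearest other 6.857), Hoxc6 at 4.786 in replicate 3 (4.125), Kcnj11 at 6.717 in replicate 4 (7.207), Id1 at 4.767 in replicate 1 (5.035) and the mean of the insulin-like growth factor axis at 8.265 in replicate 4 (7.905). In wildtype islets these were, all in replicate 5, Ctrc at 15.52 (12.75), Ms4a1 at 5.312 (4.025) and the lymphocyte mean at 5.324 (4.826).

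The stromal list was lower in heterozygous islets. Its mean of -0.72 was -0.82 with the 3' minus 5' difference as a covariate and -0.77 with the acinar mean. Neither covariate, as measured, thus accounted for the difference. This does not exclude RNA degradation or acinar carry-over. Many acinar genes are compressed near the top of the range. The 3' minus 5' difference stood apart only in heterozygous replicates 3 and 4, which held the lowest and the highest stromal mean. Fewer stromal cells in the preparations could account for the lower stromal list. Of 219 genes outside the lists that tracked the stromal mean within genotype (r over 0.8), 192 were lower (87.7%). Of all genes outside the lists, these 219 included, 45.1% were lower. This test does not separate fewer cells from lower expression of stromal genes in each cell, or from chance differences between the mice. Genotype remains open as an untested biological explanation. With the stromal mean as a covariate the endothelial difference was -0.056, duct -0.042, growth factor axis -0.11 and hedgehog -0.038. The same drop may account for these 4, but this covariate cannot single it out. The stromal mean itself differed between the genotypes. It correlated with the endothelial, growth factor axis and hedgehog means at r = 0.877, 0.919 and 0.811, so that any shared cause would shrink these differences. The immediate-early difference was -0.21 and is left without a tested explanation.

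Over 100 splits of the 10 arrays into 5 and 5, the real one included, chance cannot be excluded for the lists or for the probe sets at an unadjusted p under 0.01. As many lists were called in 29 splits (real 6, highest other 11), and as many of these probe sets came up in 36 (real 135, highest other 853). What set the split with 853 apart was not tested. The real count of probe sets called was 0 with limma (760 at an unadjusted p under 0.05, and 0 by a plain test; highest other 1), so that all 100 splits reach it by construction and it says nothing of chance. A camera p for the stromal list as small as the real one came up in 5 of the 100 splits.

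Heterozygous replicate 2 held Igha at 13.07 and Fabp1 at 12.22. Of 24 other intestinal markers, 16 (66.7%) lay over 1 log2 unit above the median of the other 9 arrays, among them Fabp2 at 12.62, Apoa1 at 11.71 and Apoa4 at 10.14, and on no other array did more than 4 (16.7%, heterozygous replicate 5). The share fell short of the 75% set beforehand and lay far above the 20% set against it, so that intestinal tissue carried along with the islets and other sources cannot be told apart by this test. What keeps it open are the other 8 markers, of which Cdx1, Rbp2, Mep1a, Muc2 and Cdx2 lay at background and Vil1, Dpp4 and Olfm4 were high on all 10 arrays. No biological explanation was tested.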

How the results depend on the processing

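The tests with the stromal mean as a covariate and without heterozygous replicates 2 and 5 were chosen after the data were seen. With limma, 0 probe sets passed in the fit reported and under each alternative run (760 at an unadjusted p under 0.05, and 0 by a plain test), and no named gene passed. The Men1 difference was negative throughout, from -0.63 to -0.28. The stromal (-0.999 to -0.56) and endothelial (-0.38 to -0.23) lists were called lower without each array in turn, and the means of duct (-0.28 to -0.16), hedgehog (-0.26 to -0.15) and growth factor axis genes (-0.37 to -0.23) stayed negative. The 6 lists called became 10 with no filter, 3 with the acinar mean, 11 with the 3' minus 5' difference and 2 with the stromal mean as a covariate, 0 with an estimated correlation, 0 with fry and 0 with permutation of the list mean, and 2 (without heterozygous replicate 5) to 10 (without wildtype replicate 3) when 1 array was left out. Further lists called lower were alpha cells, imprinted genes, myeloid cells, proliferation and TGF-beta with no filter, myeloid cells and proliferation with array weights, and acinar cells, imprinted genes, proliferation, TGF-beta and Wnt targets with the 3' minus 5' difference as a covariate. The 2 with the stromal mean were immediate-early genes and, in addition, acinar cells (-0.14). The loss of the stromal call there says nothing, since a list's own mean as a covariate brings its mean difference to 0 by construction. The 135 probe sets at an unadjusted p under 0.01 became 226 with the acinar mean as a covariate, 87 without heterozygous replicates 2 and 5, and 92 (without wildtype replicate 1) to 284 (without heterozygous replicate 4) when 1 array was left out. The replicate block called 0 probe sets, gave 152 at an unadjusted p under 0.01, 8 lists, proliferation and TGF-beta in addition, and -0.47 for Men1, and changed no other call. Deviations from the genotype means correlated between same-numbered arrays at 0.108, -0.043, -0.284, 0.032 and 0.106. Only number 5 correlated best with its own number, so that these values gave no sign that the numbers pair the mice.

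Differences that reversed were small or uncalled. With the stromal mean as a covariate these were Anxa1 0.034, Apcdd1 0.060, Ccnd1 0.17, Cdh19 0.17, Cdkn1b -0.041, Cdkn2c 0.059, Hhex 0.039, Hoxc6 -0.0051, Lmo2 0.13, Sst 0.017, Tgfbr2 0.061, and the list means of delta, PP and epsilon cells 0.11, endocrine progenitors 0.033, myeloid cells 0.11, proliferation 0.042, TGF-beta 0.10 and Wnt 0.13. With the 3' minus 5' difference as a covariate they were Cdh19 0.25, Mki67 -0.17, Rbp4 0.016, Sst 0.15, beta cells 0.097 and delta, PP and epsilon cells 0.10. With the acinar mean they were Cdkn1b -0.0076 and secretory granules -0.049. With array weights they were Mki67 -0.061, prolactin -0.015 and secretory granules -0.0097. After quantile normalization they were G1 genes -0.0047, prolactin -0.0089 and secretory granules -0.011, and after median centring prolactin -0.0096 and secretory granules -0.013. Without heterozygous replicates 2 and 5 they were Cdkn2c 0.029, Ppy -0.12, acinar cells 0.031, prolactin -0.059 and secretory granules -0.026. Ms4a1 (-0.087) and lymphocytes (-0.40) also turned there, by the choice of these arrays, which were left out for high lymphocyte markers. When 1 array was left out the ranges that crossed 0 were Cdh19 -0.37 to 0.27, Cdkn1b -0.14 to 0.14, Cdkn2c -0.077 to 0.063, Kcnj11 -0.28 to 0.0014, Mki67 -0.085 to 0.19, Ppy -0.054 to 0.30, Sst -0.17 to 0.070, acinar cells -0.11 to 0.050, beta cells -0.11 to 0.088, CDK inhibitors -0.0057 to 0.11, delta, PP and epsilon cells -0.090 to 0.079, endocrine progenitors -0.068 to 0.015, G1 genes -0.011 to 0.062, myeloid cells -0.27 to 0.015, prolactin -0.041 to 0.076 and secretory granules -0.073 to 0.063. Ranges that kept their sign and had an end over 1.5 times above or below the value on all 10 arrays were Adm -0.55 to -0.27, Apcdd1 -0.48 to -0.21, Ccnd1 -0.30 to -0.0035, Ccnd3 -0.36 to -0.15, Cdkn1c -0.43 to -0.21, Ctrc -0.86 to -0.029, Dnajc3 0.24 to 0.45, E2f1 0.14 to 0.29, Fabp4 -0.47 to -0.14, Gria3 0.093 to 0.32, Hhex -0.26 to -0.048, Hoxc6 0.021 to 0.21, Ins2 -0.070 to -0.027, Insm1 0.26 to 0.69, Isl1 -0.28 to -0.046, Lmo2 -0.72 to -0.30, Ms4a1 0.57 to 1.35, Ncam1 0.021 to 0.21, Nkd1 -0.50 to -0.20, Rab27a 0.095 to 0.21, Rbp4 -0.27 to -0.073, Reg1 -0.064 to -0.016, Slc2a1 0.097 to 0.39, Socs3 -0.39 to -0.081, Stat5b 0.064 to 0.21, Vamp2 -0.27 to -0.091, alpha cells -0.13 to -0.054, p53 genes 0.045 to 0.11, endoplasmic reticulum stress 0.061 to 0.14, hypoxia 0.019 to 0.098, immediate-early genes -0.34 to -0.059, imprinted genes -0.19 to -0.096, lymphocytes 0.11 (without heterozygous replicate 2) to 0.73, menin complex -0.075 to -0.027, proliferation -0.23 to -0.036, TGF-beta -0.32 to -0.14 and Wnt targets -0.25 to -0.066. Apart from Ms4a1 and lymphocytes without heterozygous replicates 2 and 5, the cause was not tested. Signal over background limits dim genes: 18567 of 45037 probe sets passed the filter.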

Other observations

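The relations between lists and the genes named in this part were chosen after the data were seen, and the test of the genes next to Men1 was set before its result was seen.

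Acinar transcripts were among the brightest on these arrays. Cela3b, Clps, Zg16, Cela2a, Cpb1 and Cpa1, which encode digestive enzymes and secretory proteins, stood at 17.1, 17.0, 16.8, 16.8, 16.7 and 16.6 over all 10 arrays, and the islet hormone genes Gcg, Iapp and Ins2 at 16.4, 16.3 and 16.3. Levels of different probe sets near the top of the range do not rank transcripts by abundance. Over the 10 mice the acinar mean correlated with the beta cell mean at r = -0.792 (permutation p = 0.00405, -0.589 without the 2 mice farthest out) and with the secretory granule mean at r = -0.894 (permutation p = 0.0001, -0.848 without these 2). The stromal mean correlated with the endothelial mean at r = 0.877 (permutation p = 0.00084) and with the beta cell mean at r = -0.117 (permutation p = 0.744). These are 4 of 6 relations tested, and the first 3 passed adjustment over the 6.

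In 14 probe sets the genotypes differed by more than 2-fold at an unadjusted p under 0.05, and none passed adjustment over all probe sets. The only higher one was that of Ppp1r3b, a glycogen-targeting subunit of a phosphatase (1.24, SE 0.31). All others were lower, among them the vessel genes Mmrn1 (-1.79, SE 0.41) and Lyve1 (-1.07, SE 0.34). The matrix genes Fbln5 (-1.17, SE 0.37) and Fbln1 (-1.02, SE 0.37) were also among the lower ones. The female-specific transcript Xist was lowest in wildtype replicate 2 on each of its probe sets. On the brightest it stood there at 10.89, against 11.49 to 12.49 on the other arrays. On another it stood at 9.94 against 11.01 to 12.37, and on the dimmest at 6.81 against 8.28 to 9.23. Eif2s3y and Kdm5d of the Y chromosome lay at background on all 10. Lymphocyte markers over 1 log2 unit above the median of the other 9 arrays numbered 7 of 13 in heterozygous replicate 2, 5 in heterozygous replicate 5, 3 in wildtype replicate 5 and 0 on the other arrays.

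A hypothesis tested was that strain-derived DNA linked to the targeted allele makes the genes next to Men1 differ between the genotypes. The median absolute t of the 100 nearest measured genes was 0.573, at percentile 14.8 of 8088 random stretches of neighbouring genes (median 0.6495). This argues against a difference across many of these genes. A median hardly moves with a few changed genes, so linked DNA that alters a few of them was not excluded. Of these neighbours 3 had an unadjusted p under 0.05, among them Pacs1 (0.40), chosen after its value was seen.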
